A study of Mus musculus with 18 samples.

How the data were processed

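RNA was measured by sequencing in NK cells sorted from pooled spleens of C57BL/6 mice. The cells came from wild-type mice (WT) or from tamoxifen-treated mice with an inducible Cre recombinase in the Ncr1 gene, a Cre-dependent YFP reporter and floxed Eomes alleles (called KO here). Each preparation was separated by surface CD27 and CD11b. CD27 alone marked stage II, both proteins marked stage III, and CD11b alone marked stage IV, which gave 6 groups of 3 libraries, or 18 libraries. Per the labels' protocols, 8 to 12 week old mice were treated for 3 days, and the work was done in 3 separate experiments. The labels do not say which replicate number belongs to which experiment, nor how many mice were pooled. The WT label gives no further genotype, so whether WT mice carried Cre is not stated. The treatment protocol is listed for WT and KO samples alike, but whether WT mice received tamoxifen is uncertain. If they did not, its effect cannot be told apart from that of the deletion.

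Per the submitters' processing notes, the authors used STAR 2.0.4 and featureCounts 1.4.5 from the Subread package. The genome build, the read type and the strand setting are not given in the sources used here. Per the file headers, each deposited file lists an Ensembl gene, its position and length, and 3 values: a raw count of reads, a CPM and an RPKM. The authors' CPM equals the deposited count divided by the library's own total and rescaled, with a largest relative difference of 5e-15 over all genes with a count. The authors' RPKM equals that CPM per kilobase of the listed length, within 6.6e-14. The raw count was the only one of the 3 values used here, since the other two are rescaled from it.

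All 18 files listed the same 41388 genes. Of these, 40340 had an ID in the GENCODE M21 annotation of GRCm38, and 40195 overlapped their position there, so positions are given on GRCm38. A gene symbol was found for 40254 IDs, and 8 symbols were shared by several IDs, which were kept apart by ID. Total counts ran from 18684350 to 28365837 per library. PCR copies cannot be told from separate molecules in these counts, so the stated errors come from the spread between libraries.

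Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with too few counts were removed by edgeR's filter by group, which left 14156 genes. Libraries were scaled by the trimmed mean of M values, and 1 quasi-likelihood model with a mean for each of the 6 groups was fitted to all 18 libraries, so that the groups shared their estimate of the spread. The contrasts were KO against WT within each stage, the differences of that effect between stages (interaction), WT stage III against II, IV against III and IV against II, and KO stage IV against II. P-values were adjusted over the tested genes by Benjamini and Hochberg's method, and a gene was called changed at an adjusted p under 0.05. Unless another tool is named, an adjusted p of a gene is from this edgeR test. Standard errors were taken as the absolute log2 fold change divided by the square root of the F statistic, which is an approximation. Fitted log2 fold changes used a prior count of 0.125. The design, the gene lists, the rule for naming genes and the first set of alternatives were chosen before the data were examined.

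The 21 gene lists held 383 genes: cytotoxic effectors, cytokines and chemokines, immature NK markers, mature NK markers, Ly49 receptors, other NK receptors, NK transcription factors, ILC1 markers, apoptosis regulators, IL-2 and IL-15 signalling, trafficking receptors, cell cycle, interferon response, immediate early and stress genes, glycolysis, oxidative phosphorylation, B cell markers, T cell markers, myeloid markers, erythroid and platelet markers, and mitochondrially encoded transcripts. Some genes stood on more than 1 list. For each list the members called changed were counted, and counted again with p-values adjusted over the list alone. Limma's camera (version 3.58.1) compared each list with all other genes at a preset correlation of 0.01 and again at a correlation estimated from the data, with adjustment over the lists of a contrast. Limma's fry tested whether a list's genes moved one way on balance, without comparing them with other genes. Unless said otherwise, an adjusted p of a list is from camera, with the preset correlation first.

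Genes that change with maturation in WT cells were also followed after Eomes deletion. Each such set was called between 2 WT stages and read in the KO against WT change of the remaining stage, so the libraries compared do not overlap. The model shared its estimate of the spread over all 18 libraries, so the remaining stage still affected the calls. WT stage IV against II went from 2135 to 2619 genes without KO stage III replicate 1. Those sets also come from the same series, so they are not independent evidence.

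Genes were named by a fixed rule: Eomes in every library; for each KO against WT contrast and for WT stage IV against II, the 10 highest and 10 lowest log2 fold changes among called genes with an average log2 CPM of at least 3, no overlap between the groups' libraries, and no predicted gene name. Chance alone separates 3 libraries from 3 for 10% of genes. For interactions, the 5 smallest adjusted p in each direction were named. From each list, up to 4 members with the smallest adjusted p were named, and 15 genes of NK cell biology were given for KO against WT in each stage whatever their result. Other members of a list are named only where the called ones are few, a choice made after their values were seen. The values of some list members are not reported here.

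Alternatives were DESeq2's size factors or upper-quartile scaling in edgeR, no filter on low counts, a stricter filter (at least 1 CPM in at least 6 libraries), DESeq2 1.42.0 (Wald test), limma-voom, the replicate number as a block, only the libraries of the contrast, and each library of the contrast's groups left out in turn. A block for replicate within genotype was added for contrasts between stages. After the data were seen, more were added: leaving out in turn each library from outside a contrast, leaving out 2 libraries with few detected genes, leaving out 2 with many genes at 1 to 5 counts, leaving out these 4, voom with sample quality weights, and the mean expression of 4 Y-linked genes as a covariate. For WT, libraries with the same replicate number deviated together between stages: the correlation of their deviations from the group means was between 0.131 and 0.485 for all pairs, so the numbers were taken to pair WT libraries across stages. That pairing comes from the data, since the labels do not state it.

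The procedure was tested on simulated counts drawn from the real libraries' means and sizes, with 200 genes changed by known factors. For KO against WT in stage II (13938 genes tested), 1.6% of genes changed 1.5-fold, 41.8% of those changed 2-fold and 59.1% of those changed 4-fold were recovered. For stage III (13934 genes) the shares were 11.7%, 40.0% and 70.5%, and for stage IV (13898 genes) 7.9%, 36.9% and 65.5%. Each of these 3 simulated comparisons made 5 false calls. Simulated lists of 20 changed genes in these comparisons had p between 3.76e-09 and 1.92e-07 with the estimated correlation, and lists of unchanged genes between 0.172 and 0.714. Genes were drawn independently, each with the same spread in all groups. The simulation thus held no correlation between genes, no shared replicate effect and no library that stood apart. It does not show how the list test or the stage III calls behave when these are present. At this depth and number of replicates, most genes changed 2-fold or less were missed.

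Counts of families with near-identical copies, such as the Ly49 (Klra), Khdc1, Bcl2a1, Apol7 and H2 genes, and of Ugt1a genes, which share exons, are uncertain because shared reads cannot be assigned to 1 member. Antisense and overlapping genes are uncertain too, since the strand setting is not stated. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the figures.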

Results

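The series asks which genes Eomes, a T-box transcription factor of NK cells, regulates at each stage of NK cell maturation. RNA from sorted splenic NK cells was sequenced in 18 libraries: 3 each of WT and KO cells at stage II, stage III and stage IV. Stage II cells carry CD27 without CD11b, stage III cells carry both proteins, and stage IV cells carry CD11b without CD27. According to the labels the spleens were pooled and the work was done in 3 separate experiments, but the labels do not say which replicate number belongs to which experiment. Total counts ran from 19409764 to 21789075 in WT stage II, from 21942834 to 26092733 in KO stage II. They ran from 21681639 to 28365837 in WT stage III, from 19898606 to 24909877 in KO stage III, and from 20428503 to 24641981 in WT stage IV and from 18684350 to 25147639 in KO stage IV.

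Some libraries stood apart from the others of their group. KO stage III replicates 1 and 3 had counts for 14824 and 16536 genes, against 21454 in KO stage III replicate 2, and their 10 most abundant genes took 17.0% and 20.6% of the counts, against 10.6%. Voom's sample quality weights were 0.1705, 0.1557 and 0.3238 in KO stage III replicates 1, 2 and 3, the lowest of the 18 libraries. WT stage II replicate 1 and KO stage IV replicate 3 had counts for 29859 and 27912 genes, of which 10135 and 9854 had only 1 to 5 counts. Xist, a transcript of female cells, was at 0.636 CPM or less in replicates 2 and 3 of all WT stages, and between 5.66 and 45.2 CPM in the other 12 libraries, so the pools differed in the sex of their mice. The summed CPM of immediate early and stress genes was 4662 to 5839 in all replicate 1 libraries, 5226 in KO stage III replicate 3, and 8096 to 15227 in the remaining libraries.

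Eomes (ENSMUSG00000032446, chromosome 9, 118478212 to 118486132, GRCm38) had fewer counts in every KO library than in any WT library of the same stage. In stage II the counts were 3710, 4335 and 4631 in WT and 1440, 1777 and 1310 in KO. In stage III they were 6227, 7101 and 7487 in WT and 3181, 3488 and 3375 in KO, and in stage IV 5974, 5842 and 5620 in WT and 2254, 2750 and 2194 in KO. The log2 fold change was -1.70 ± 0.15 (SE, n = 3 per genotype) in stage II, or 3.26-fold lower, -0.69 ± 0.15 in stage III (1.61-fold lower) and -1.28 ± 0.15 in stage IV (2.43-fold lower). All 3 passed edgeR's quasi-likelihood test (adjusted p = 1.15e-05, 0.0143 and 2.74e-04). The counts cover the whole gene, and which exons are floxed is not given in the sources used here, so they do not measure how many cells lost a functional allele. The stage III call ended without WT stage III replicate 1, 2 or 3 or KO stage III replicate 1, without the 2 libraries with few genes, with only the stage III libraries and with voom quality weights, over a range of -0.85 to -0.62.

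**Figure D1:**
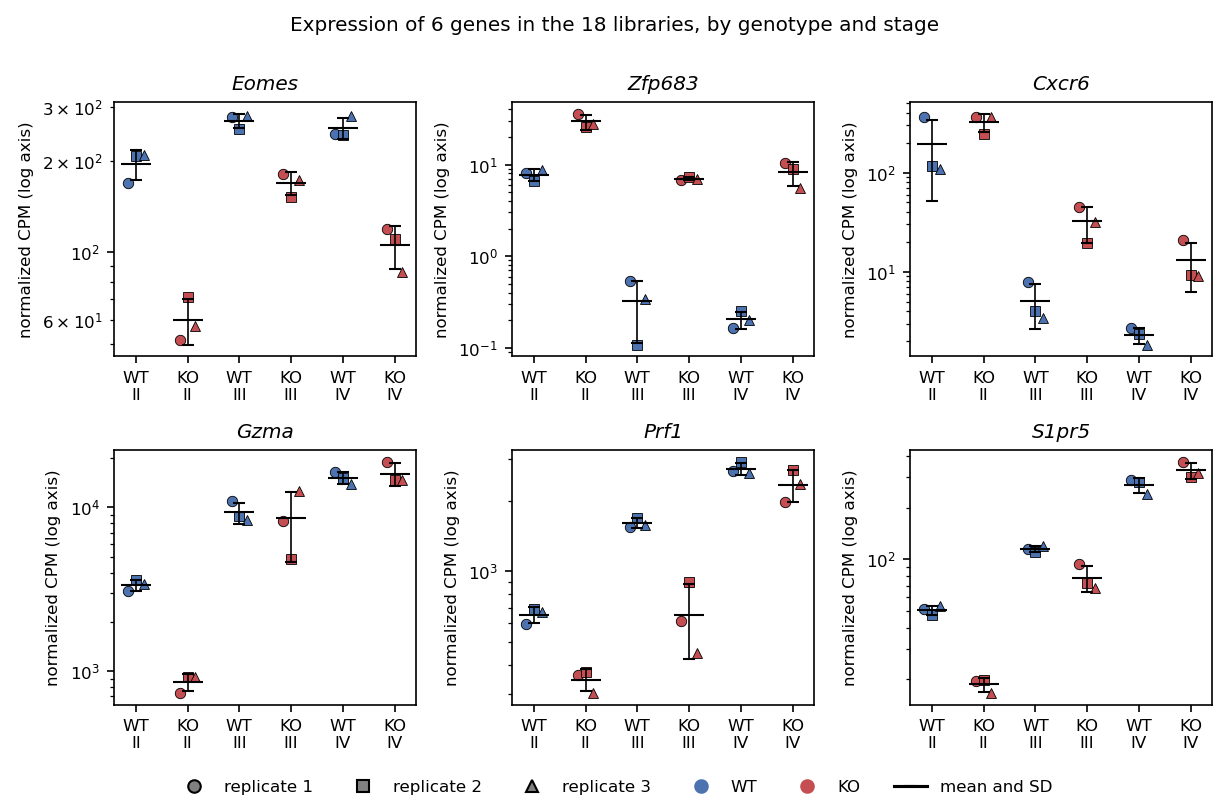
Normalized CPM (log axis) of Eomes, Zfp683, Cxcr6, Gzma, Prf1 and S1pr5 in each of the 18 libraries by genotype and stage, with the group mean and SD (n = 3). Mean Zfp683 was 29.6 CPM in KO and 7.77 in WT stage II, and 8.25 in KO and 0.205 in WT stage IV.

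In stage II, RNA of the cytotoxic and mature NK lists was lower in KO, and RNA of markers of type 1 innate lymphoid cells (ILC1) was higher. RNA of a sorted population cannot tell a change within cells from a change in the mix of cells, such as the share of ILC1. This holds for all stages. Zfp683 (Hobit), a transcription factor of tissue-resident lymphocytes, was 3.80-fold higher (log2 1.93 ± 0.28, n = 3 per genotype). Gzma, the gene of granzyme A, was lower by log2 -1.97 ± 0.25, and Prf1, which encodes the pore-forming protein perforin, by -0.92 ± 0.19. S1pr5, a receptor for exit from marrow and lymph node, was lower by -1.44 ± 0.14. In total 207 of 14156 tested genes changed, 66 higher and 141 lower, and 133 of them by at least 2-fold.

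The largest rises in stage II by the naming rule were of Zfp683, Crybg2 (1.84 ± 0.30), Itga1 (1.79 ± 0.31), which encodes the collagen-binding integrin CD49a, and Cd200r2 (1.67 ± 0.25). They were followed by Lgals3 (1.61 ± 0.26), the galectin-3 gene, S100a4 (1.60 ± 0.18), a calcium-binding protein, and Cish (1.53 ± 0.18), an inhibitor of STAT5 signalling. Nebl (1.45 ± 0.20), Gsn (1.43 ± 0.29), the actin-severing gelsolin, and Tmem176a (1.35 ± 0.26) came next. The largest falls were of Rhpn1 (-6.66 ± 0.72), with 3, 4 and 0 counts in the KO libraries, Cd300lf (-4.72 ± 0.56), an inhibitory receptor, Khdc1b (-4.58 ± 0.46) and Ugt1a7c (-4.55 ± 0.55). Gzmk (-3.28 ± 0.64), a granzyme, St5 (-3.22 ± 0.28), the mast cell chymase gene Cma1 (-3.21 ± 0.41), the adhesion molecule Mcam (-3.12 ± 0.33), the protease gene Cym (-2.74 ± 0.25) and Myb (-2.66 ± 0.47), a transcription factor of progenitors, followed.

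Of 18 cytotoxic effectors, 4 fell and 1 rose (7 and 2 adjusted over the list alone): Gzma, Gzmm (-1.81 ± 0.24), Gzmk and Prf1 fell, and the death ligand Tnfsf10 rose (0.92 ± 0.19). As a list they were lower (adjusted p = 4.38e-06, and adjusted p = 0.00452 with an estimated correlation). Of 14 mature NK markers, 5 fell and none rose (8 and 0 adjusted over the list alone, adjusted p = 6.76e-13, and 9.60e-05 with an estimated correlation), among them S1pr5, Cma1, the repressor Prdm1 and the inhibitory receptor Klrg1 (-1.28 ± 0.25). Of 12 Ly49 receptors, which bind MHC class I, 7 fell and none rose (9 and 0 adjusted over the list alone), led by Klra8 (-1.26 ± 0.18), Klra4 (-1.24 ± 0.19) and Klra1 (adjusted p = 2.86e-22, and 0.00452 with an estimated correlation). Of 18 ILC1 markers, 5 rose and none fell (11 and 0 adjusted over the list alone): Zfp683, Itga1, Tmem176b (1.25 ± 0.18), Tmem176a and Tnfsf10 (adjusted p = 7.49e-16, and 8.80e-04 with an estimated correlation).

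Trafficking receptors went both ways in stage II. Of 20, 4 fell, among them S1pr5 and the chemokine receptor Ccr2 (-1.06 ± 0.12). Itgb7 (0.85 ± 0.14) and Itga1 rose (7 and 2 adjusted over the list alone, adjusted p = 4.45e-05, and adjusted p = 0.0925 with an estimated correlation). Of 14 immature NK markers 2 fell, among them the protease inhibitor Ctla2a (-1.57 ± 0.18, 3 higher and 2 lower adjusted over the list alone, adjusted p = 0.372). Of 25 other NK receptors, Klrb1b rose (0.98 ± 0.13) and Slamf6 (-1.52 ± 0.26), Klrc3 and Klre1 fell (4 and 6 adjusted over the list alone, adjusted p = 0.480). Of 32 NK transcription factors, Ikzf2 (1.16 ± 0.13), Zfp683 and Maf (1.04 ± 0.20) rose, and Myb, Prdm1 and Irf8 fell (3 and 4 adjusted over the list alone, adjusted p = 0.641, with a median of 0.013 and a mean of -0.036). In IL-2 and IL-15 signalling, Cish and Socs2 (1.01 ± 0.23), both induced by STAT5, rose and the kinase Jak1 fell (-0.58 ± 0.12) among 18 genes (3 and 1 adjusted over the list alone, adjusted p = 0.0683).

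The death receptor Fas (0.82 ± 0.19) was the 1 of 25 apoptosis regulators that rose (1 adjusted over the list alone, adjusted p = 0.0551). This list passed its test in 16 of 18 fits with 1 library left out and in 4 of 13 other settings. IL-2 and IL-15 signalling did so in 17 of 18 and in 2 of 13. Ifit1 (0.94 ± 0.21) was the 1 of 20 interferon response genes that rose (2 adjusted over the list alone, adjusted p = 2.50e-04, and adjusted p = 0.119 with an estimated correlation). The cell cycle list was lower (adjusted p = 8.29e-05) with 0 of 26 genes called by edgeR (0 adjusted over the list alone, 3 at an unadjusted p under 0.05), but its adjusted p was 0.524 with an estimated correlation, and the call ended without WT stage II replicate 2. Cd79b (1.16 ± 0.25), a B cell receptor component, rose among 11 B cell markers (1 adjusted over the list alone, adjusted p = 0.842, median 0.12, mean -0.63). Of 12 T cell markers Camk4 rose (1.34 ± 0.28) and Cd3d fell (-1.54 ± 0.23, 1 and 1 adjusted over the list alone, adjusted p = 0.397). EdgeR called 0 genes among cytokines and chemokines, immediate early and stress genes, glycolysis, oxidative phosphorylation, myeloid markers, erythroid and platelet markers and mitochondrially encoded transcripts (1, 0, 1, 0, 2, 0 and 0 at an unadjusted p under 0.05, 1, 0, 1, 0, 1, 0 and 0 by DESeq2), with adjusted p of 0.710, 0.688, 0.172, 0.593, 0.372, 0.480 and 0.490. Tbx21, which encodes the related factor T-bet, was at log2 0.12, Gzmb at -0.74, Ifng at 0.18, Itgam at -1.20, Cd27 at -0.17, Zeb2 at -0.90, Bcl2 at -0.10, Mcl1 at -0.01, Bcl2l11 at 0.26, Il2rb at -0.38 and Ncr1, where Cre is inserted, at -0.55, none of which passed the test.

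The stage II count was 105 without WT replicate 2, 106 without WT replicate 3, 133, 127 and 107 without KO replicates 1, 2 and 3, and 325 without KO stage III replicate 1. Of the genes named, calls that ended when some single libraries were left out were those on Gsn (5 of 18 libraries, log2 1.38 to 1.54), Tmem176a (2, 1.30 to 1.54), Gzmk (3, -3.50 to -3.13), Tnfsf10 (4, 0.83 to 1.14), and Prf1 (5, -0.98 to -0.82). So did those on Klrg1 (2, -1.42 to -1.10), Prdm1 (5, -1.15 to -0.82), Klrc3 (14, -0.70 to -0.48), Klre1 (15, -0.91 to -0.77), and Maf (3, 0.98 to 1.20). The last were Fas (6, 0.67 to 1.06), Jak1 (12, -0.67 to -0.49), Socs2 (5, 0.89 to 1.22), Ifit1 (3, 0.81 to 1.27), Cd79b (4, 1.07 to 1.27) and Camk4 (4, 1.17 to 1.63), and all kept their direction.

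In stage III ILC1 markers were again higher in KO. Genes that rise with maturation went both ways: Itgam, Cma1 and Prf1 fell, and Ly6c2 and Ccl5 rose. As a list, mature NK markers were lower with the preset correlation (camera adjusted p = 0.00313) but not with an estimated one (0.0505). Zfp683 was 21.8-fold higher in KO (log2 4.44 ± 0.37, n = 3 per genotype), and Cxcr6, a chemokine receptor of tissue-resident lymphocytes, was higher by 2.66 ± 0.49. Prf1 was lower by log2 -1.29 ± 0.19, and Itgam, which encodes CD11b, by -1.35 ± 0.32. Gzma, at -0.13, did not pass the test. Of 14156 genes, 1119 changed, 730 higher and 389 lower, and 440 of them by at least 2-fold. The excess of rises was not kept with voom (527 higher, 622 lower) or without KO replicate 2 (2456 and 2537). This number rests on libraries that stood apart: it was 162 without KO replicates 1 and 3, which had few detected genes (this leaves 1 KO library), 10 when only the stage III libraries were fitted, and 4993 without KO replicate 2.

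By the naming rule the largest rises in stage III were of Zfp683, Crybg2 (4.22 ± 0.35), Aqp9 (3.74 ± 0.36), a water and glycerol channel, and the homing receptor Gpr15 (3.48 ± 0.38). Next came the chemokine Ccl9 (3.08 ± 0.84), S100a4 (2.84 ± 0.19), Tmem176a (2.75 ± 0.29), Apol7b (2.66 ± 0.44), Cxcr6 and Lgals3 (2.63 ± 0.26). Falls were led by Khdc1b (-3.79 ± 0.39), Ugt1a7c (-3.64 ± 0.54), Cd300lf (-3.55 ± 0.53), Rhpn1 (-3.42 ± 0.51), and St5 (-2.63 ± 0.26). Next came Myb (-2.42 ± 0.47), Mcam (-2.28 ± 0.29), Cpq (-2.20 ± 0.64), Camk2n1 (-2.05 ± 0.23), an inhibitor of CaM kinase II, and Entpd1 (-1.91 ± 0.32), the ectonucleotidase CD39.

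Of 18 ILC1 markers, 12 rose and none fell in stage III (14 and 0 adjusted over the list alone, adjusted p = 4.83e-18, and 0.00121 with an estimated correlation). They included Tmem176b (2.31 ± 0.19), Il7r (1.86 ± 0.29), the IL-7 receptor gene, Itga1 (1.83 ± 0.32), Cxcr6, Il2ra (1.77 ± 0.35) and Tnfsf10 (1.15 ± 0.20). Of 14 mature NK markers, 8 fell and 2 rose (9 and 2 adjusted over the list alone, adjusted p = 0.00313, and adjusted p = 0.0505 with an estimated correlation). Prdm1 (-1.04 ± 0.20), Spn (-0.63 ± 0.12), Cma1 (-1.71 ± 0.37), Irf8, Itgam, Itgb2, S1pr5 (-0.56) and Klrg1 (-0.86) fell. Ly6c2 (1.64 ± 0.31) and the chemokine Ccl5 (0.95 ± 0.24) rose. Among 18 cytotoxic effectors, Prf1, Stx11 (-0.74) and Serpinb9 fell and Tnfsf10, Gzmc (1.78 ± 0.36) and Srgn rose (5 and 5 adjusted over the list alone, adjusted p = 0.662). Of 10 cytokines and chemokines, Lta (2.40 ± 0.42), Tnf (1.72 ± 0.37) and Ccl5 rose (3 adjusted over the list alone, adjusted p = 0.0224, and adjusted p = 0.567 with an estimated correlation). That list call ended without WT stage III replicate 1 or KO stage III replicate 2.

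Transcription factors changed in both directions in stage III: Zfp683, Ikzf2 (1.12 ± 0.13), Id3 (2.19 ± 0.28) and Tcf7 (0.94 ± 0.18), a factor of early NK cells, rose. Ikzf3 (-1.06 ± 0.13), Prdm1, Myb, Irf8 and Ikzf1 fell (8 and 8 of 32 adjusted over the list alone, adjusted p = 0.554, median -0.022, mean 0.13). Of 20 trafficking receptors, 7 fell, led by Ccr2 (-1.20 ± 0.12), and 4 rose, Itgb7 (0.84 ± 0.14), Itga1, Cxcr6 and Itgb1 (8 and 5 adjusted over the list alone, adjusted p = 0.195, median -0.19, mean 0.053). Of 14 immature NK markers, Il7r, Ly6e and Tcf7 rose and 1 fell (3 and 3 adjusted over the list alone, adjusted p = 0.120). Klra5 (1.09 ± 0.24) was the 1 of 12 Ly49 receptors called (1 adjusted over the list alone, adjusted p = 0.298). Of 25 other NK receptors Cd7, Cd160 and Lag3 rose and Klrc3 fell (3 and 1 adjusted over the list alone, adjusted p = 0.195). In IL-2 and IL-15 signalling Cish (1.18 ± 0.18), Il2ra and Socs2 rose and Jak1 fell (5 and 3 adjusted over the list alone, adjusted p = 0.638, median -0.14, mean 0.15). Of the interferon response genes 5 of 20 rose, such as Ifit1 (1.05) and Rtp4 (1.11), and Irf7 fell (5 and 2 adjusted over the list alone, adjusted p = 0.0732). Bcl2a1d (1.46) rose among 25 apoptosis regulators (0 adjusted over the list alone, adjusted p = 0.466). Of 15 glycolysis genes Hk2 (1.88 ± 0.38) rose and Slc2a1 and Pfkp fell (1 and 6 adjusted over the list alone, adjusted p = 0.120).

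Some B cell markers were also higher in KO stage III. Of 11 B cell markers, Cd79b (1.73 ± 0.26), H2-Aa (2.44 ± 0.59) and Cd74 (2.10 ± 0.56) rose (5 adjusted over the list alone, adjusted p = 0.00444, and adjusted p = 0.386 with an estimated correlation). The B cell list call ended without KO replicate 2. The summed CPM of the B cell markers was 907, 1104 and 1187 in KO and 766, 781 and 719 in WT stage III. In stage II this sum was higher in KO too (2148, 2010 and 2127, against 1728, 1686 and 1503 in WT). In stage IV it was lower in KO (225, 171 and 232, against 241, 326 and 364 in WT). Of 12 T cell markers, Cd3g rose (6 adjusted over the list alone, adjusted p = 0.0333, and adjusted p = 0.141 with an estimated correlation). The T cell list call ended without WT stage III replicate 3 or KO stage III replicate 1 or 2, and with the replicate block. EdgeR called 0 of 14 myeloid and 0 of 9 erythroid and platelet markers (3 and 3 at an unadjusted p under 0.05, 1 and 0 by DESeq2), with means of log2 1.73 and 1.37 and adjusted p of 0.195 and 0.120. It also called 0 of 26 cell cycle and 0 of 18 immediate early and stress genes (2 and 0 at an unadjusted p under 0.05, 2 and 0 by DESeq2, adjusted p = 0.412 and 0.812). Of 20 oxidative phosphorylation genes 3 rose, Uqcrq (0.91), Cox5a (0.71) and Atp5e (0.81), with 13 higher and 1 lower adjusted over the list alone (adjusted p = 8.64e-04, and adjusted p = 0.567 with an estimated correlation). Without the 2 libraries with few detected genes the mean of that list was -0.13. Of 8 mitochondrially encoded transcripts mt-Nd1 rose (0.70 ± 0.19, 2 adjusted over the list alone, adjusted p = 0.0224, and adjusted p = 0.567 with an estimated correlation). The mitochondrial list call ended without WT or KO stage III replicate 1. Tbx21 (0.21), Gzmb (-0.37), Ifng (-0.07), Cd27 (-0.01), Zeb2 (-0.73), Bcl2 (-0.51), Mcl1 (0.29), Bcl2l11 (0.14), Il2rb (-1.27) and Ncr1 (-0.77) did not pass the test.

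The stage III count was 235, 168 and 144 without WT replicates 1, 2 and 3, and 371 and 352 without KO replicates 1 and 3 (4993 without KO replicate 2). Libraries of other stages also moved it: it was 516 and 525 without WT stage II replicates 2 and 3, 596, 539 and 539 without KO stage II replicates 1, 2 and 3. It was 585, 486 and 542 without WT stage IV replicates 1, 2 and 3, and 672 and 569 without KO stage IV replicates 1 and 2. Of the 20 genes named by size, Crybg2, S100a4, Lgals3 and St5 passed the test in all 31 other settings. The others ended with only the stage III libraries. Ccl9 and Cpq ended in 17 and 21 of the 31, 13 and 16 of them with 1 library left out. The direction was kept throughout by these 20. Among list members, calls that ended without some single libraries were those on Gzmc (4 of 18, log2 1.29 to 1.98), Tnf (3, 1.42 to 2.14), Ccl5 (5, 0.05 to 1.24), Cma1 (4, -2.44 to -1.36), and Klrg1 (15, -1.11 to -0.62). Others were Itgam (5, -2.03 to -0.56), S1pr5 (4, -0.70 to -0.50), Il2ra (1, 1.43 to 1.96), Klra5 (4, 0.29 to 1.37), Cd160 (4, 0.63 to 1.06), and Lag3 (16, 0.52 to 1.67). The same held for Klrc3 (16, -0.54 to -0.32), Jak1 (14, -0.55 to -0.34), and Socs2 (16, 0.39 to 0.92). Further such calls were those on Bcl2a1d (14, 1.17 to 1.72), Hk2 (2, 1.46 to 2.07), Slc2a1 (4, -0.88 to -0.41), Pfkp (5, -1.39 to -0.44), H2-Aa (3, 1.63 to 3.30), Cd74 (13, 1.26 to 3.00), Cd3g (15, 0.48 to 1.19), Uqcrq (10, -0.01 to 1.20), Cox5a (14, -0.03 to 0.97) and Atp5e (17, -0.09 to 1.09).

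In stage IV the list of ILC1 markers was higher in KO, with 2 of 18 members called. The fall of the cytotoxic and mature NK lists seen in stage II was not detected. Zfp683 was 39.2-fold higher in KO (log2 5.29 ± 0.39, n = 3 per genotype), and Cxcr6 was higher by 2.48 ± 0.52. Markers of immature NK cells fell, among them Thy1 (-2.07 ± 0.19), Ctla2a (-1.70 ± 0.18) and Cd27 (-0.92 ± 0.18), whose protein was used to sort the cells. Gzma (0.09), Gzmb (0.14), Prf1 (-0.23), Klrg1 (0.25), Itgam (-0.10) and S1pr5 (0.28) did not pass the test. Nor did Tbx21 (0.30), Ifng (-0.81), Zeb2 (0.24), Bcl2 (0.09), Mcl1 (0.09), Bcl2l11 (0.41), Il2rb (-0.42) and Ncr1 (-0.74). In total 72 genes changed, 34 higher and 38 lower, and 55 of them by at least 2-fold.

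The largest rises in stage IV were of Zfp683, Crybg2 (4.81 ± 0.37), Cxcr6, Parm1 (2.31 ± 0.49), the semaphorin receptor Nrp1 (2.29 ± 0.28), Tnfsf8 (2.23 ± 0.36), which encodes CD30 ligand. Next came the transporter Slco3a1 (2.17 ± 0.18), Tnf (2.15 ± 0.44), Jaml (2.02 ± 0.38) and Nebl (1.67 ± 0.20). The largest falls were of Ugt1a7c (-3.89 ± 0.55), Cd55 (-2.10 ± 0.25), which protects cells from complement, Thy1, Arl5c (-1.92 ± 0.23) and St5 (-1.79 ± 0.24). Ctla2a, Khdc1b (-1.62 ± 0.35), the chemokine receptor Cxcr3 (-1.49 ± 0.27), the prostaglandin receptor Ptger2 (-1.45 ± 0.24) and Mcam (-1.31 ± 0.28) followed.

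Of 14 immature NK markers, Thy1, Ctla2a, Cxcr3 and Cd27 fell and none rose in stage IV (7 lower and 3 higher adjusted over the list alone, adjusted p = 1.80e-11, and 0.0290 with an estimated correlation). Of 18 ILC1 markers, Zfp683 and Cxcr6 rose and none fell (6 and 0 adjusted over the list alone, adjusted p = 4.33e-10, and 0.0134 with an estimated correlation). Itgb7 (1.07 ± 0.14) and Cxcr6 rose and Cxcr3 fell among 20 trafficking receptors (4 and 3 adjusted over the list alone, adjusted p = 0.0722). Srgn (0.87 ± 0.18), the granule proteoglycan, rose among cytotoxic effectors (1 adjusted over the list alone, adjusted p = 0.922). Tnf rose among cytokines and chemokines (1 higher and 1 lower adjusted over the list alone, adjusted p = 0.489), and Klra5 (1.14 ± 0.24) among Ly49 receptors (1 adjusted over the list alone, adjusted p = 0.378). Zfp683 rose among NK transcription factors (3 adjusted over the list alone, adjusted p = 0.378) and Socs2 (1.19 ± 0.25) among IL-2 and IL-15 genes (1 adjusted over the list alone, adjusted p = 0.784). Tigit (-1.21 ± 0.26), an inhibitory receptor, fell among other NK receptors (2 higher and 2 lower adjusted over the list alone, adjusted p = 0.0891). Mean and median lay on different sides of 0 for cytotoxic effectors (-0.013 and 0.007), NK transcription factors (0.15 and -0.035), IL-2 and IL-15 genes (0.046 and -0.005), interferon response (0.076 and -0.014), immediate early and stress genes (0.10 and -0.18) and T cell markers (-0.22 and 0.019). EdgeR called 0 mature NK markers (5 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by voom, adjusted p = 0.489). It also called 0 interferon response genes (4 at an unadjusted p under 0.05), 0 T cell markers (2) and 0 apoptosis, glycolysis, B cell and myeloid genes (1 each), and 0 in the cell cycle, immediate early, oxidative phosphorylation, erythroid and mitochondrial lists (0 each), all with 0 by DESeq2. These 11 lists had adjusted p from 0.378 to 0.999 except for mitochondrially encoded transcripts (adjusted p = 0.0246, and adjusted p = 0.799 with an estimated correlation).

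Single libraries moved the stage IV count: it was 33, 33, 42, 30 and 35 without WT replicates 2 and 3 and KO replicates 1, 2 and 3. It was 44 and 46 without WT stage II replicates 2 and 3, 47 and 43 without KO stage II replicates 2 and 3, 39 and 43 without WT stage III replicates 2 and 3, and 110 without KO stage III replicate 1. Calls that ended with some libraries left out were those on Cxcr6 (10 of 18, log2 1.96 to 2.68), Parm1 (12, 2.08 to 2.48), Tnf (13, 1.68 to 2.67), Jaml (5, 1.74 to 2.32), and Khdc1b (14, -1.76 to -1.49). So did those on Cxcr3 (4, -1.89 to -1.28), Ptger2 (2, -1.58 to -1.40), Mcam (15, -1.40 to -1.19), and Srgn (13, 0.71 to 1.03), and those on Cd27 (12, -1.13 to -0.78), Klra5 (15, 1.06 to 1.17), Tigit (15, -1.35 to -1.04) and Socs2 (14, 0.89 to 1.32), all with an unchanged direction.

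**Figure D2:**
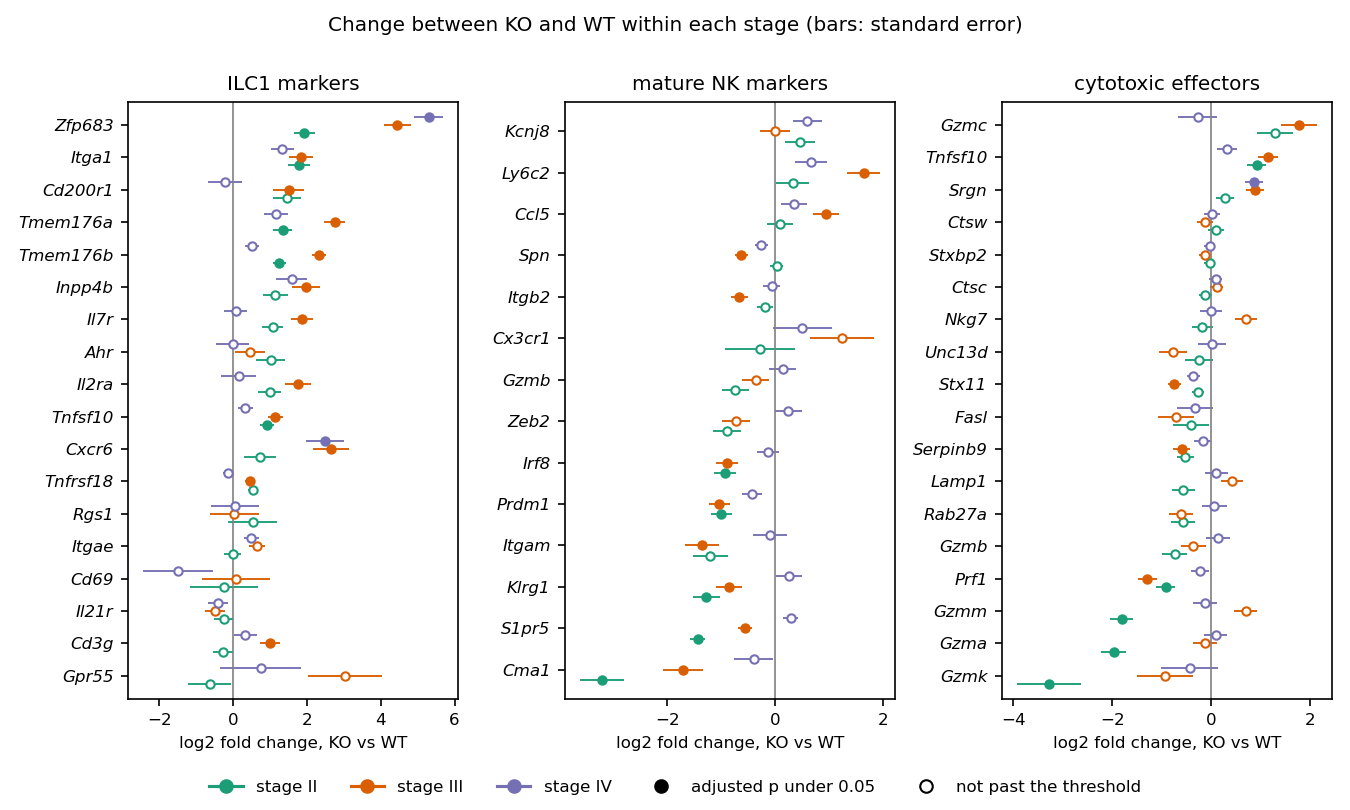
Log2 fold change of KO against WT with its standard error (n = 3 per genotype) for the members of the ILC1, mature NK and cytotoxic lists in stages II, III and IV, with filled points for an adjusted p under 0.05. Points to the right are higher in KO. Zfp683 was at 1.93, 4.44 and 5.29, and Gzma at -1.97, -0.13 and 0.09 in stages II, III and IV.

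Across stages, 26 genes changed in the same direction in all 3. Rises were shared by Nebl, S100a4, Zfp683, Crybg2, Slco3a1, Socs2, Tspan31, 1700017B05Rik, Rmnd5b and Itgb7, and falls by Eomes, Khdc1a, Khdc1b, Gm16328, Ugt1a7c, Cd55, Fcrl6, Gpr174, Dpysl5, St5, Mcam, Sept4, Arl5c, Igf2r, H2-Q10 and Gtf2a1l. Naming all 26 was decided after their values were seen. The number was 4 with only the libraries of each contrast. It was 16 without WT stage II replicate 3, WT stage III replicate 2, WT stage IV replicate 2 or 3 or KO stage IV replicate 2 or 3, and 17 without WT stage III replicate 3. Stages II and III shared 39 genes higher and 67 lower in KO, against 3.40 and 3.87 for independent lists of the same size. Libraries with the same number deviated together across stages in WT, and in KO between stages II and III, so independent lists are not the level without an effect. Stages II and IV shared 10 and 20 (0.159 and 0.378 for independent lists), and stages III and IV shared 32 and 22 (1.75 and 1.04).

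The effect of the deletion was tested for a difference between stages. The loss of S1pr5 in stage II was not seen in stage IV. Its KO effect was higher by log2 1.72 ± 0.19 in stage IV than in stage II (edgeR adjusted p = 0.00117). That of Gzma was higher by 2.06 ± 0.34 (adjusted p = 0.0193), that of Ccr2 by 1.19 ± 0.16, that of As3mt by 1.67 ± 0.23, and those of Zfp683 and Crybg2 by 3.37 ± 0.49 and 2.97 ± 0.46. Mean Zfp683 was lower in stage IV than in stage II in both genotypes and near the floor in WT stage IV. Its larger ratio there is thus not a larger amount of RNA. Zfp683 and Crybg2 are neighbours on the same strand of chromosome 4 and are not shown to be independent. Thy1 (-1.90 ± 0.26), Apol7e (-1.21 ± 0.20), Cd200r2 (-2.56 ± 0.44), Slc27a6 (-2.34 ± 0.41) and Ptger2 (-1.84 ± 0.33) had a lower KO effect in stage IV than in stage II. In total 30 genes differed, 23 with a higher and 7 with a lower effect. The lists of mature NK markers (adjusted p = 1.34e-12, and 1.04e-04 with an estimated correlation), Ly49 receptors (1.45e-13, and 0.0321), cytotoxic effectors (7.11e-05, and 0.0210) and trafficking receptors (9.90e-08, and 0.0347) had a higher effect in stage IV. EdgeR called 0 of 12 Ly49 receptors in this contrast (9 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by voom, 8 adjusted over the list alone).

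Between stages III and II, 7 genes differed. Cym (2.97 ± 0.33), Gzmm (2.51 ± 0.33), Cd3d (2.27 ± 0.33), Capn3 (2.54 ± 0.39) and Id3 (2.25 ± 0.37) had a higher and Slc27a6 (-2.42 ± 0.40) and Entpd1 (-2.68 ± 0.45) a lower effect in stage III. Ly49 receptors and T cell markers had a higher effect in stage III as lists (adjusted p = 3.94e-15 and 0.00250, and 0.0394 for both with an estimated correlation). EdgeR called 0 of 12 Ly49 receptors (11 at an unadjusted p under 0.05, 8 by DESeq2 and 0 by voom, 10 adjusted over the list alone) and 1 of 12 T cell markers (4 adjusted over the list alone). ILC1 markers had a higher effect too (adjusted p = 1.14e-04), but not with an estimated correlation (adjusted p = 0.0878), and edgeR called 0 of 18 (7 at an unadjusted p under 0.05, 2 by DESeq2 and 0 by voom, 6 adjusted over the list alone). Between stages IV and III, 4 genes differed. Ccr2 (1.33 ± 0.16) had a higher and Tmem176b (-1.81 ± 0.26), Thy1 (-1.62 ± 0.26) and Car2 (-1.22 ± 0.20) a lower effect in stage IV. With an estimated correlation, mature NK markers were higher (adjusted p = 0.0188), and immature NK, ILC1 and T cell markers lower (adjusted p = 0.0323, 0.0188 and 0.0188) in that contrast. There edgeR called 0 of 14 mature NK markers (10 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom, 7 adjusted over the list alone) and 0 of 12 T cell markers (4, 0, 0 and 0 in the same order).

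The 7 genes of stage III against II became 2, 3, 4 and 4 without WT stage II replicates 2 and 3 and KO stage II replicates 1 and 3. They became 2 and 2 without WT stage III replicates 2 and 3, 2443 and 11 without KO stage III replicates 2 and 3, 4 without WT stage IV replicate 3 and 4 without KO stage IV replicate 2. The 30 of stage IV against II became 8, 6, 9 and 2 without WT stage II replicates 2 and 3 and KO stage II replicates 1 and 3. They became 18, 5 and 3 without WT stage IV replicates 1, 2 and 3, 17 and 8 without KO stage IV replicates 2 and 3. Libraries of stage III moved them too, to 18 and 19 without WT stage III replicates 2 and 3, and 66, 62 and 46 without KO stage III replicates 1, 2 and 3. The 4 of stage IV against III became 2440 without KO stage III replicate 2, 0 without WT stage III replicate 1. They became 1 or 2 without WT stage III replicate 2 (1) or 3 (2), KO stage III replicate 1 (2) or 3 (2), WT stage IV replicate 2 (1) or 3 (1), KO stage IV replicate 2 (1) or 3 (1) and WT stage II replicate 1, 2 or 3 (2 each). In this contrast 1461 genes had an unadjusted p under 0.05 in the test on all libraries. Without some single libraries the calls ended for Cd3d (3 of 18, log2 1.54 to 2.51), Capn3 (7, 1.72 to 2.74), Id3 (11, 1.79 to 2.44), Slc27a6 (9, -2.88 to -1.85) and Entpd1 (10, -3.25 to -2.42) between stages III and II. They ended for Ccr2 (1, 1.25 to 1.46), Tmem176b (6, -1.99 to -1.40), Thy1 (13, -1.75 to -1.35) and Car2 (14, -1.37 to -0.83) between stages IV and III. Between stages IV and II they ended for Gzma (8, 1.90 to 2.18), Ccr2 (1, 1.09 to 1.30), and As3mt (3, 1.53 to 1.82), Zfp683 (2, 3.15 to 3.59), Crybg2 (3, 2.68 to 3.25), Apol7e (7, -1.35 to -1.15), Cd200r2 (8, -3.02 to -2.43), Slc27a6 (9, -2.57 to -2.24) and Ptger2 (8, -2.09 to -1.66).

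Maturation itself was read from WT stage IV against stage II. Mature NK markers were higher in stage IV and immature NK markers lower. Cx3cr1, the fractalkine receptor, was higher by log2 5.85 ± 0.69, Entpd1 by 5.09 ± 0.36, Cma1 by 4.47 ± 0.42, Klrg1 by 4.19 ± 0.28 and Itgam by 3.81 ± 0.35 (n = 3 per stage). Gpx8 (4.92 ± 0.65), Cdc20b (4.35 ± 0.24), Kcnj8 (3.92 ± 0.31), Sept5 (3.67 ± 0.32) and Ccl9 (3.53 ± 0.88) rose with them. The Notch ligand Dll1 (-6.60 ± 0.64), Apol7b (-6.53 ± 0.46), Cxcr6 (-6.39 ± 0.58), Lta (-6.12 ± 0.52), and Il7r (-6.00 ± 0.35) fell most. Tcrg-C4 (-5.97 ± 0.29), Ccdc184 (-5.86 ± 0.56), Gpr34 (-5.82 ± 0.41), Ltb (-5.76 ± 0.65) and Jaml (-5.76 ± 0.37) were next. Of 14156 genes, 745 were higher and 1390 lower in stage IV. In the single steps, 420 genes changed from stage II to III (140 higher, 280 lower) and 449 from stage III to IV (108 higher, 341 lower).

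All 14 mature NK markers rose and 13 of 14 immature NK markers fell from WT stage II to IV (14 and 13 adjusted over the list alone, adjusted p = 2.87e-07 and 1.61e-05 with an estimated correlation). Of 18 ILC1 markers, 15 fell and 1 rose (15 and 1 adjusted over the list alone, adjusted p = 5.29e-06 with an estimated correlation), and Zfp683 was lower by -5.21 ± 0.39. Cytotoxic effectors split, with 7 higher, such as Gzmb (3.12 ± 0.27) and Prf1 (2.07 ± 0.20), and 4 lower, such as Gzmm (-3.16 ± 0.26) and Tnfsf10 (-2.89 ± 0.21, 8 and 5 adjusted over the list alone, adjusted p = 0.138). Interferon response genes fell in 14 of 20 cases and rose in 1 (15 and 1 adjusted over the list alone), led by Oas3 (-3.43 ± 0.33) and Ifit1 (-2.00 ± 0.22, adjusted p = 6.22e-10, and 0.0163 with an estimated correlation). B cell markers fell in 6 of 11 cases and T cell markers in 9 of 12 (6 and 10 adjusted over the list alone, adjusted p = 0.0357 and 1.61e-05 with an estimated correlation). The summed CPM of B cell markers was 1503 to 1728 in WT stage II and 241 to 364 in WT stage IV. Of 26 cell cycle genes 12 fell, such as Ccnb2 (-3.66 ± 0.80, 13 adjusted over the list alone, adjusted p = 1.87e-04, and adjusted p = 0.380 with an estimated correlation). Of the other lists, 5 of 10 cytokines and chemokines fell and 2 rose (adjusted p = 1.80e-04, and adjusted p = 0.111 with an estimated correlation). Of 25 other NK receptors 10 fell and 2 rose (1.66e-06, and 0.110 with an estimated correlation), and 6 of 18 IL-2 and IL-15 genes fell (0.00189, and 0.0730 with an estimated correlation). Tbx21 rose by 0.84, and Eomes, at 0.39, did not pass the test.

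Libraries that moved the WT counts by over 1.5 times were WT stage II replicate 2 (1309) and WT stage IV replicates 1, 2 and 3 (1293, 1289 and 1309) for stage IV against II. For stage III against II the count was 268, 277 and 258 without WT stage II replicates 1, 2 and 3 and 247, 204 and 211 without WT stage III replicates 1, 2 and 3. For stage IV against III it was 249, 238, 270, 263, 235 and 243 without WT stage III replicates 1, 2 and 3 and WT stage IV replicates 1, 2 and 3, and 699 without KO stage III replicate 1. With the replicate number as a block, the cytotoxic list passed its test in WT stage IV against II (adjusted p = 0.0230).

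KO cells also differed between stages II and IV. Mice were treated for 3 days, so KO stage IV cells may have reached that stage before the deletion. This contrast therefore does not show maturation without Eomes, and KO cells also kept part of their Eomes RNA. Between KO stage II and IV, 866 genes were higher and 1240 lower in stage IV. Of the 745 genes higher in WT stage IV, 521 were also called higher in KO, and of the 1390 lower, 886 were also lower. Gzma rose by log2 4.23 ± 0.27, Gzmb by 3.99 ± 0.28, S1pr5 by 4.14 ± 0.15 and Cma1 by 7.28 ± 0.48 from KO stage II to IV. Eomes itself rose by 0.82 ± 0.15 (adjusted p = 7.70e-04). All 14 mature NK markers rose (14 adjusted over the list alone), and 9 of 12 Ly49 receptors rose and none fell (9 and 0 adjusted over the list alone, adjusted p = 2.17e-08 and 0.0295 with an estimated correlation).

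Genes that change with maturation in WT cells moved against that change in KO cells of stages III and IV. Of the 745 genes that rose from WT stage II to IV, 37.9% were higher in KO stage III (51.1% of all genes). Of the 1390 that fell, 69.6% were higher (adjusted p = 0.0135 and 6.65e-04, camera with an estimated correlation). In KO stage IV, 30.0% of the 140 genes that rose from WT stage II to III were higher, and 72.1% of the 280 that fell (52.8% of all genes, adjusted p = 0.0291 and 9.93e-04). Over all genes, the stage IV change fell with average abundance (Spearman rho -0.282, against 0.014 in stage III and 0.196 in stage II). The stage III change fell with gene length (Spearman rho -0.22, against 0.023 in stage IV and -0.009 in stage II). The sets were matched for neither abundance nor length, so the part of these trends in the shares was not tested. Fixed lists that fall with WT maturation split in KO stage IV. ILC1 markers were higher, but immature NK markers were lower (camera adjusted p = 1.80e-11, and 0.0290 with an estimated correlation). In KO stage II, 49.1% of the 108 genes that rose from WT stage III to IV were higher (49.1% of all genes), with 6 called higher and 18 lower (adjusted p = 0.0226). Of the 341 that fell, 47.5% were higher (adjusted p = 0.506).

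These set tests also rested on single libraries. For the rising genes in stage III the call ended without 12 of the 18 libraries. These were WT stage II replicate 2 (36.7% higher) or 3 (36.5%), KO stage II replicate 2 (37.2%) or 3 (36.9%), WT stage III replicate 1 (37.3%), 2 (36.9%) or 3 (39.7%), KO stage III replicate 1 (39.2%) or 2 (40.9%), WT stage IV replicate 1 (36.6%) or 2 (37.2%) and KO stage IV replicate 1 (37.2%). For the rising genes in stage IV it ended without 8: WT stage II replicate 3 (32.5%), WT stage III replicate 1 (35.8%) or 2 (35.7%), KO stage III replicate 2 (30.0%), WT stage IV replicate 1 (33.1%) or 2 (34.9%) and KO stage IV replicate 1 (33.8%) or 3 (36.3%). In stage II it ended without 12 of the 18 libraries. These were WT stage II replicate 1 (55.6%) or 3 (48.8%), KO stage II replicate 1 (48.4%), 2 (51.2%) or 3 (51.8%), WT stage III replicate 1 (53.1%), KO stage III replicate 1 (57.8%), 2 (52.0%) or 3 (53.8%), WT stage IV replicate 1 (48.3%) or 2 (51.0%) and KO stage IV replicate 1 (49.4%). The 2 falling sets of stages III and IV passed the test without any 1 library.

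**Figure D3:**
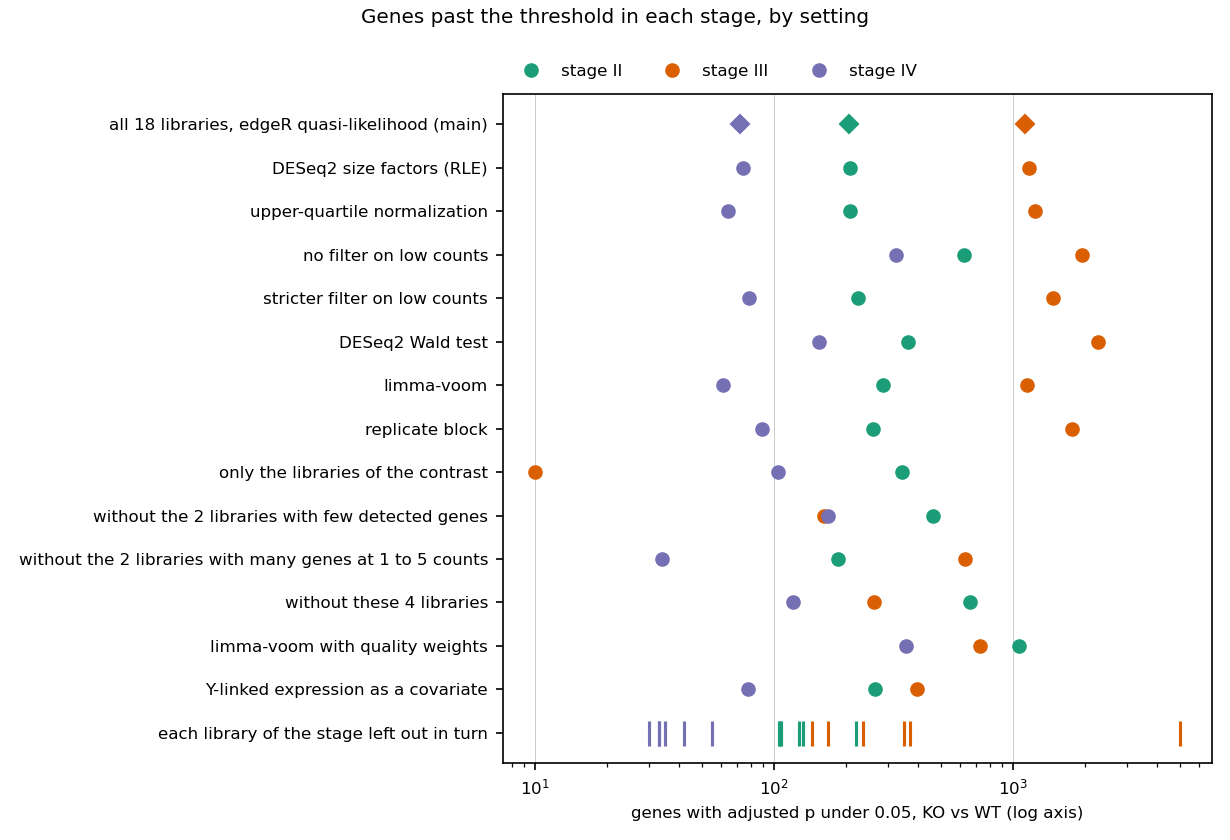
Number of genes with an adjusted p under 0.05 between KO and WT (log axis) in stages II, III and IV for each setting (diamonds: the model on all 18 libraries, circles: alternatives, bars: each library of the stage left out). The stage III count was 1119 in the model on all libraries, 10 with only the stage III libraries and 4993 without KO replicate 2, while stage II ran from 105 to 1061 and stage IV from 30 to 358.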

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

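The 2 tests of the smaller KO effect in stage IV were chosen after the result was seen, and the bound of the first was tightened after its value was known, which turned its outcome from argued against to open. The settings with the Y-linked covariate, with quality weights and without the few-gene or many-gene libraries were chosen after seeing the data, as was the naming of the 26 genes. Each gene below was singled out because the effect of Eomes deletion differed between 2 stages in a test of that difference (log2 ± SE, edgeR).

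Between stages III and II the differences were Cym 2.97 ± 0.33, Gzmm 2.51 ± 0.33, Cd3d 2.27 ± 0.33, Capn3 2.54 ± 0.39, Id3 2.25 ± 0.37, Slc27a6 -2.42 ± 0.40 and Entpd1 -2.68 ± 0.45. Between stages IV and II they were S1pr5 1.72 ± 0.19, Ccr2 1.19 ± 0.16, As3mt 1.67 ± 0.23, Zfp683 3.37 ± 0.49, Crybg2 2.97 ± 0.46, Thy1 -1.90 ± 0.26, Apol7e -1.21 ± 0.20, Cd200r2 -2.56 ± 0.44, Slc27a6 -2.34 ± 0.41 and Ptger2 -1.84 ± 0.33. Between stages IV and III they were Ccr2 1.33 ± 0.16, Tmem176b -1.81 ± 0.26, Thy1 -1.62 ± 0.26 and Car2 -1.22 ± 0.20.

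More genes passed the threshold between KO and WT in stage III (1119) than in stages II and IV. A trend of each library with gene length or abundance is argued against as the whole cause, since removing it left 697 and 1416 genes in stage III, against 171 and 187 in stage II. The 2 KO stage III libraries with few detected genes could account for much of the count: of the genes called from KO replicates 1 and 3, 60.06% kept their sign in KO replicate 2 alone, although both comparisons use the same WT libraries, which raises that share even without a change, and their median log2 change was 0.895 in the first and 0.057 in the second. A larger effect of the deletion in stage III stays open on weak evidence: KO replicate 2 as the only KO library gave 204 genes in stage III, 138 in stage II and 46 in stage IV, in a fit that assumes that this lone library varies like the other groups. KO stage III replicate 2 is not a clean reference either. Voom's quality weight for it was 0.1557, the lowest of the 18 libraries, against 0.1705 and 0.3238 for KO stage III replicates 1 and 3. The Y-linked covariate lowered the stage III count, by the value given below, so a part of the sex mix is not excluded. The excess is not shown to be biological, since stage II exceeded stage III with only the contrast's libraries (345 against 10) and with quality weights (1061 against 730). Eomes itself also fell least in stage III, by the log2 fold changes given above.

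Of the 26 genes changed in the same direction in all 3 stages, 4 passed the threshold in all 3 with only the libraries of each contrast. The sex mix of the pools is argued against as the cause for most of the 26, since 23 remained past the threshold in all 3 stages with Y-linked expression as a covariate. Of the 26, 1 lies on X or Y, but this cannot show a sex effect on other chromosomes. The mix was tied in part to genotype. Xist was at 0.636 CPM or less in WT replicates 2 and 3 and at 5.66 CPM or more in every KO library. A part of the sex mix is therefore not excluded. DNA flanking the engineered loci is argued against too as the main cause for these 26, since 0 of the 25 genes other than Eomes lie within 10 Mb of Eomes, Ncr1 or Rosa26. That window held 2.38% of tested genes, so a small part could not be seen in 25 genes. Among all calls other than Eomes it held 2.91%, 2.24% and 7.04% in stages II, III and IV. A part of flanking DNA in other stage IV calls is therefore not excluded. An effect of Eomes deletion on the 26 genes remains a hypothesis, found and tested on the same data. Effects of Cre and of tamoxifen were not tested. The labels do not say whether WT mice carried Cre, and whether they received tamoxifen is uncertain.

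The smaller or opposite KO effect in stage IV than in stage II, as for S1pr5 and Gzma, could come from fewer late-stage cells in the KO stage II gate or from less loss of Eomes in stage IV. The first cannot be told apart: of the genes that rise from WT stage III to IV, 50.93% were lower in KO stage II, close to the share of all genes, yet 18 of its genes were called lower and 6 higher. The set as a whole was placed lower (adjusted p = 0.0226), but this call ended without 12 of the 18 libraries, with voom (adjusted p = 0.143), only the contrast's libraries (adjusted p = 0.329) or the Y-linked covariate (adjusted p = 0.127), and without the few-gene libraries, the many-gene libraries or all 4. Its direction was reversed without a filter (adjusted p = 0.586) and with quality weights (adjusted p = 0.224). Nor can the second explanation be told apart, since the difference of the Eomes log2 change between stages IV and II was 0.423 (95% interval -0.028 to 0.874).

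With 3 libraries against 3 there are only 10 splits of the same libraries, too few to exclude chance, and the labelled split was the 1 that called the most genes: 207, 1119 and 72 genes for KO against WT in stages II, III and IV, 420, 449 and 2135 for the WT contrasts and 2106 for the KO contrast, with a highest other of 0. For the differences between stages the splits do not decide: 11 of 100 splits called as many genes as the 7 of stage III against II (highest other 781), 6 as many as the 30 of stage IV against II (highest other 78) and 10 as many as the 4 of stage IV against III (highest other 583). Splits that call many genes point to structure among the samples: the one with 781 keeps the genotypes apart but swaps them in 1 stage. All of the others that called as many, except 1 for stage IV against III, keep the genotypes of at least 1 stage apart, so they hold the effect of genotype and do not show chance. Of the 81, 85 and 79 splits that mix the genotypes in both stages, 0, 0 and 1 called as many (highest other count 1, 1 and 306), but in these the effect of genotype adds to the spread within groups, which can lower their counts.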

How the results depend on the processing

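The settings that leave out 2 or 4 named libraries, use quality weights, use the Y-linked covariate or leave out 1 library from outside a contrast were chosen after seeing the data; the rest were planned, except for the count of genes changed in all 3 stages. Of 329 named gene calls, 328 were kept with DESeq2's size factors, 319 with upper-quartile scaling, 320 without a filter, 329 with the stricter filter, 328 with the DESeq2 test, 302 with voom, 328 with the replicate block, 246 with only the contrast's libraries, 282 without the few-gene libraries and 309 with the covariate. Of 42 list calls, 22 were kept with an estimated correlation. Some lists short of the threshold passed it when 1 library was left out. Examples were interferon response in stage III (13 of 18 libraries) and other NK receptors in stage IV (12 of 18). In simulated counts at this depth, 36.9% to 41.8% of 2-fold changes were recovered between KO and WT. Unless the setting has fewer samples or tests other genes, the cause was not tested.

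Counts that moved by over 1.5 times are given by setting. Counts for KO against WT come first, in the order stages II, III, IV (207, 1119 and 72 in the model on all libraries), then differences of the effect for III against II, IV against II and IV against III (7, 30 and 4), then WT III against II, IV against III and IV against II (420, 449 and 2135) and KO IV against II (2106). Upper-quartile scaling gave 2 for the difference IV against III. It raised the share of higher calls from 71.4% to 85.7% for III against II and from 25% to 50% for IV against III. No filter gave 623, 1941 and 323, then 290, 1671 and 331, and 734 for WT III against II. The stricter filter gave 14 for III against II. DESeq2 gave 365, 2274 and 154, then 113, 150 and 57, and 660 and 737 for the WT steps. Limma-voom gave 10 for IV against II and 2 for IV against III.

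Only the libraries of the contrast gave 345 in stage II, 10 in stage III, 2, 113 and 0 for the differences, and 1014, 1459 and 3663 for WT. Without the 2 libraries with few detected genes, which leaves 1 KO library in stage III that is assumed to vary like the other groups, the counts were 463, 162 and 168, then 2 and 123 for the first 2 differences, 909, 1022 and 3596 for WT and 3355 for KO. Without the 2 libraries with many genes at 1 to 5 counts they were 629 in stage III, 34 in stage IV, 13 for IV against II, 1 for IV against III and 254 for WT III against II. Without these 4 libraries they were 663, 263 and 120, then 165 for IV against II, 1 for IV against III, 870, 1266 and 3647 for WT and 3461 for KO. Voom quality weights gave 1061, 730 and 358, then 39, 274 and 7, 1830, 2526 and 5155 for WT and 4191 for KO. The Y-linked covariate gave 397 in stage III and 54 for IV against II.

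With the replicate block the count was 1770 in stage III and 46 for IV against II, and the replicate block within genotype gave 12, 59 and 12 for the differences. KO libraries are not shown to be paired with WT libraries of the same stage and number (correlations of -0.099 to 0.167). Yet KO stage II and III libraries each correlated best with the WT stage IV library of their own number. In all 6 groups, replicate 1 also had the lowest summed CPM of immediate early and stress genes and of ILC1 markers. KO stage III replicate 3 was close to it in both sums (5226 against 4662, and 1595 against 1502). Replicate 1 thus differed in both genotypes in these sums, and the model on all libraries held no block for it. The block ended the T cell list call in stage III and brought the trafficking list past the threshold in stage IV. For the paired WT contrasts it moved no count by over 1.5 times; within genotype it ended the transcription factor list call of WT IV against II. DESeq2 was not run on lists or maturation sets, and the block within genotype was not run on KO against WT, where it cannot be fitted.

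The maturation sets (share higher in KO) moved as follows. Without a filter the falling set lost its call in stage III (60.2%) and stage IV (76.4%), and the rising set in stage II was at 50.3%, with its direction reversed. That rising set also lost its call with voom (49.6%), only the contrast's libraries (54.9%), without the few-gene libraries (56.6%), without the many-gene libraries (54.3%), without these 4 (56.5%) and with the covariate (54.0%), and was reversed with quality weights (57.8%). In stage IV the rising set lost its call without the many-gene libraries (47.1%). The rising set in stage III lost its call with only the contrast's libraries (38.2%). The falling set in stage II passed the threshold without the 4 libraries (39.5%).

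The 26 genes changed in the same direction in all 3 stages became 68 without a filter (25 of the 26 among them), 50 with DESeq2 (26), 4 with only the contrast's libraries (4), 45 without the few-gene libraries (19), 16 without the many-gene libraries (15), 43 without these 4 (20) and 65 with quality weights (18). They ran from 16 to 39 with 1 library left out; all alternatives for this number were chosen after seeing the data.

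Without the few-gene libraries the value for Cox5a, KO vs WT, stage III was reversed (-0.0238), as were Atp5e (-0.075) and the mean of the oxidative phosphorylation list (-0.13). There the test placed the Ly49 and other NK receptor lists lower than other genes instead of higher, although their means stayed above 0 (0.0283 and 0.0041). Without the 4 libraries the reversed values were Uqcrq (-0.0065), Cox5a (-0.0349), Atp5e (-0.0864) and oxidative phosphorylation (-0.14).

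Leaving out 1 library at a time, counts ran from 105 to 325 in stage II, 144 to 4993 in stage III and 30 to 110 in stage IV. The differences ran from 2 to 2443 (III against II), 2 to 66 (IV against II) and 0 to 2440 (IV against III). The WT contrasts ran from 204 to 629, 235 to 699 and 1289 to 2619, and KO IV against II from 1429 to 2540. The rising sets ran from 33.6% to 40.9% (stage III), 26.2% to 45.2% (stage IV) and 47.7% to 57.8% (stage II).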

Other observations

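Each WT library correlated best with the WT library of its own replicate number in the other stages. So did KO stage II libraries with KO stage III (0.154, 0.313 and 0.222) and with WT stage IV (0.292, 0.184 and 0.134). The same held for KO stage III with WT stage IV (0.1, 0.147 and 0.069). Between WT stage II and KO stage III no library did (-0.125, -0.19 and 0.073). No group matched KO stage IV at every number (WT stage II: -0.372, 0.329 and -0.498). Y-linked genes were detected in all 18 libraries, among them Ddx3y at 95.1 CPM in WT stage II replicate 1 and 214 CPM in WT stage II replicate 3. Xist was at 45.2 and 0 CPM in these 2 libraries. The summed CPM of ILC1 markers was 3200, 4352 and 5500 in WT stage II replicates 1, 2 and 3, and 4480, 8530 and 6290 in KO stage II. It was 1000, 2452 and 3193 in WT stage III, and 1502, 4160 and 1595 in KO stage III. In stage IV it was 839, 2543 and 2680 in WT and 982, 3011 and 1635 in KO. The genotypes thus overlapped in this sum in each stage. The summed CPM of myeloid markers was 214 in KO stage III replicate 2, and 116 and 130 in replicates 1 and 3.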
